A study of Arabidopsis thaliana with 80 samples.

How the data were processed

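Root RNA was sequenced from Arabidopsis thaliana seedlings of the wild type Col-0 and of the mutant myb36-2. Per the labels, seedlings were raised for 7 days, moved for 7 days to plates with or without a synthetic bacterial community of 41 members (SynCom, against NB for no bacteria), and harvested at 14 days, with 10 seedlings on a plate. The labels describe independent biological replicas and an experiment repeated in separate runs, called run 1 and run 2 here. Each library was sequenced as 4 technical repeats, so that the 80 deposited samples stand for 20 libraries.

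The deposited table gives the authors' raw read counts per gene, with no normalisation, for 23397 genes. The submitters' processing notes name FastQC 0.11.8, Trimmomatic 0.36, HISAT2 2.1.0, featureCounts and the genome build TAIR10. They state neither the strand setting of the counting nor the annotation version. Gene positions, symbols and biotypes were taken here from a TAIR10.1 annotation, in which 23158 of the table's loci were found. Protein-coding genes made up 98.9% of the table's genes. Whole-number values and unequal totals between columns were checked in the table.

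The 4 technical repeats of a library were summed. Between repeats of a library, the chi-squared statistic per degree of freedom was 1.011 to 1.039, against 1.84 to 7.61 between libraries of the same group and run, so the library and not the repeat was the unit of replication. Totals per library ran from 2343089 to 5007227 counts, and totals per repeat from 575776 to 1272297. The labels state 5 replicas of each treatment in one place and 3 independent biological replicas in another, and do not say which plants make up a library. Libraries were taken as replicates, and the BioRep number in the sample titles was read as the run. Every n and the replicate block rest on this reading. Intervals from counts and the 3-count floor cover counting error only, since they use counts summed over libraries and leave out the spread between libraries. The reads carry no molecular identifiers, so repeated reads of a molecule cannot be told apart.

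Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 17262 genes. Libraries were scaled by TMM, with factors of 0.951 to 1.04, and a quasi-likelihood model was fitted to all 20 libraries with a mean for each of the 4 groups and a term for the run (the replicate block). Its residual degrees of freedom were 15 and its prior degrees of freedom 8.25. The contrasts were SynCom against NB in each genotype, myb36-2 against Col-0 in each condition, and the difference between both genotypes' SynCom responses (the interaction). Tests were two-sided. P values were adjusted by Benjamini-Hochberg within a contrast, and genes with an adjusted p below 0.05 were called. Values after ± are standard errors of the log2 fold change unless SD is written. For edgeR they were computed from the fold change and the F statistic of its test, not estimated directly. For genes with few counts in a group they can be too small. CPM (each gene's counts relative to its library's total) were computed with the TMM-scaled library sizes. Since myb36-2 NB libraries came from run 1 alone, contrasts with this group were also computed within run 1. For contrasts with this group, a fit without the replicate block mixes in the difference between runs. A call lost in that fit can therefore come from the run.

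A set of 27 gene lists with 417 members, of which 410 were in the table, was fixed beforehand. The lists cover the Casparian strip, suberin, lignin, abscisic acid (ABA) response, responses to iron, phosphate, nitrogen, sulfur and zinc supply, transport of potassium, sodium, boron and copper, pattern-triggered immunity, salicylic acid, jasmonate, ethylene, auxin response, glucosinolates, aquaporins, hypoxia, heat shock, touch, the circadian clock, photosynthesis as a marker of shoot tissue, and markers of root hairs, root cap and meristem, ground tissue, xylem and phloem. Each was compared with all other genes by camera in limma 3.58.1 on the edgeR fit, with a preset inter-gene correlation of 0.01 and adjustment over the lists within a contrast. Camera with a correlation estimated for each list, and fry, which tests a list alone, were run as alternatives. Member counts are given for adjustment over all genes and "adjusted over the list alone".

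Named genes followed a rule: MYB36 in every library; per contrast, the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 2 and the same sign in each run that holds both groups; and the called members of each list with the smallest p, up to 4 in called lists and up to 2 in others. Members of the Casparian strip, suberin, ABA and iron lists were eligible even if not called. The text leaves out some genes that the rule names. For a group with no count of a gene the fold is a bound against a floor of 3 counts over the group, and for 1 to 3 counts it is a ratio with an exact 95% interval. Bounds and ratios were first computed with the runs pooled, which ignores the run, and the choice to print them within a run instead was made after the results were seen. Both versions are kept in the results, and the genes they cover were picked on the pooled counts.

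Groups, contrasts, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The alternatives were the size factors of DESeq2 (RLE) in place of TMM, no filter or a minimum of 10 CPM in 3 libraries, DESeq2 1.42.0 and limma voom in place of edgeR, no replicate block, run 1 or run 2 alone, only the groups of a contrast, only the first technical repeat, a 2-fold threshold, and leaving out each library. Chosen after seeing the data were the fits with a mean for each group and run, which give contrasts within a run under a shared spread, and a fit without the libraries Col-0 NB S5 and Col-0 SynCom S35. The procedure was tested on simulated data with the same groups and depths. Of genes changed 2-fold it recovered 81.5% and 53.7% for the SynCom response in Col-0 and myb36-2, 61.2% and 80.3% for the genotype difference under NB and SynCom, and 39.4% for the interaction. The share of false calls was 1.7% to 7.3%. In the simulation few genes changed, genes varied independently and the run acted alike in all groups. The real data differ in these respects, so recovery and false calls there can differ.

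Further computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. All samples were used.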

Results

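Messenger RNA was counted in roots of Col-0 and myb36-2 seedlings grown with the 41-member SynCom or with no bacteria. MYB36 encodes the transcription factor that switches on the genes of the Casparian strip, the lignin band of the root endodermis, and myb36-2 is a mutant allele of it. The groups held 6 libraries of Col-0 NB, 5 of Col-0 SynCom, 3 of myb36-2 NB and 6 of myb36-2 SynCom. Run 1 gave 3 libraries to each group. Run 2 gave 3 of Col-0 NB, 2 of Col-0 SynCom, 3 of myb36-2 SynCom and none of myb36-2 NB. Total counts in Col-0 NB were 3484294 (S4), 3698626 (S5), 2731549 (S6), 4312611 (S64), 4852052 (S65) and 4963184 (S66). In Col-0 SynCom they were 3636692 (S34), 2343089 (S35), 4289735 (S36), 3901486 (S94) and 3574072 (S95). In myb36-2 NB they were 3469425 (S16), 3378234 (S17) and 3354783 (S18). In myb36-2 SynCom they were 3679098 (S46), 3455383 (S47), 3628383 (S48), 5007227 (S118), 4754716 (S119) and 4527341 (S120). The 10 most abundant genes took 6.0% to 8.3% of a library, and chloroplast genes 0.33% to 0.77%. The first principal component held 34.4% of the variance and parted the runs, and the second, with 16.9%, parted SynCom from NB within each run. On the first component, too, SynCom libraries lay apart from NB libraries of the same run, on its lower side.

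**Figure D1:**
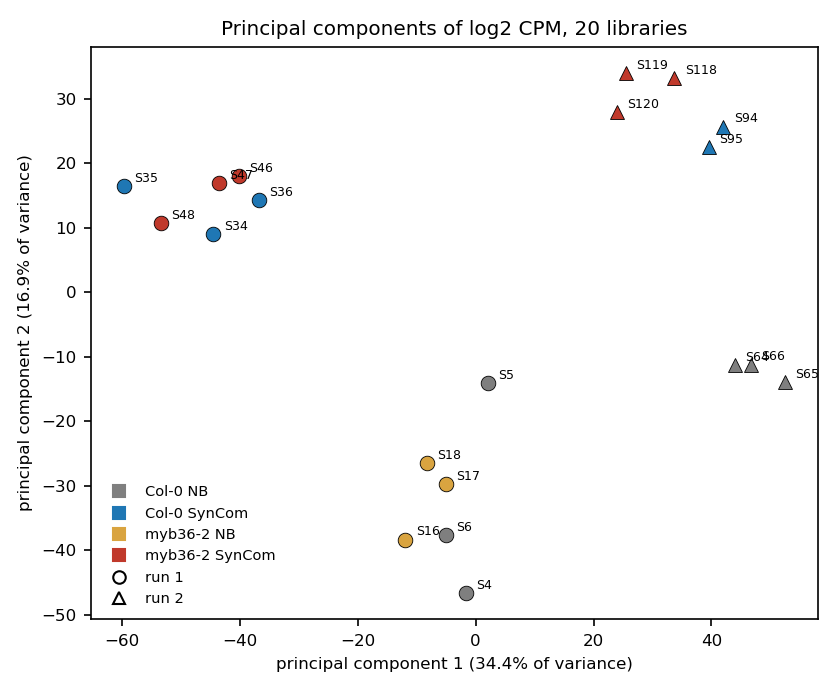
The 20 libraries on the first and second principal components of log2 CPM, in units of the component, with colour for the group and marker for the run. The components hold 34.4% and 16.9% of the variance; run 2 libraries lie to the right of run 1 libraries, and SynCom libraries lie above NB libraries.

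MYB36 (AT5G57620, chromosome 5, 23334767 to 23336632 in TAIR10.1) was still transcribed in every mutant library. It stood at 37.5 ± 6.58 CPM in Col-0 NB (SD, n = 6), 37.2 ± 4.3 in Col-0 SynCom (n = 5), 27.8 ± 5.9 in myb36-2 NB (n = 3) and 26.7 ± 2 in myb36-2 SynCom (n = 6). Its levels per library were 41.19, 28.26, 47.72, 36.56, 34.02 and 37.14 CPM in Col-0 NB S4, S5, S6, S64, S65 and S66. Col-0 SynCom S34, S35, S36, S94 and S95 had 33.61, 42.85, 34.44, 34.35 and 40.87 CPM. For myb36-2 NB S16, S17 and S18 the values were 22.91, 26.06 and 34.33 CPM, and for myb36-2 SynCom S46, S47, S48, S118, S119 and S120 they were 24.85, 26.13, 28.74, 24.13, 28.62 and 28.04 CPM. The log2 fold change of MYB36 between genotypes was -0.44 ± 0.16 under NB (adjusted p = 0.246) and -0.47 ± 0.12 under SynCom (adjusted p = 0.0556). Neither passed the test adjusted over all genes. Adjusted over the Casparian strip list alone, where many members fell, MYB36 passed as lower in both conditions. Under SynCom all 6 mutant libraries lay below all 5 Col-0 libraries. MYB36 was called under SynCom without Col-0 NB S5 (adjusted p = 0.0348), Col-0 NB S6 (0.0352), Col-0 SynCom S34 (0.0495), myb36-2 NB S16 (0.0473) or myb36-2 NB S18 (0.0442), and by DESeq2 (0.0281). Counts of the locus do not tell mutant from normal transcript.

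The question of the first comparison, myb36-2 against Col-0 without bacteria, is which root genes differ with the MYB36 genotype. Many genes of the Casparian strip fell. CASP1 (AT2G36100) and CASP2 (AT3G11550) encode membrane proteins that mark the site of the strip, and had log2 fold changes of -7.20 ± 0.31 and -7.60 ± 0.32 (n = 3 against 6, adjusted p = 9.37e-14 and 5.18e-14). CASP1 stood at 93.6 ± 18.8 CPM in Col-0 NB and 0.691 ± 0.171 in myb36-2 NB (SD). With so few counts in the mutant, the standard error of its fold change can be too small. The peroxidase gene PER64, which acts in lignin formation of the strip, changed by -5.14 ± 0.28 and the dirigent gene DIR16 by -5.60 ± 0.44. A dirigent-like gene outside the list, AT3G55230, had the largest fitted fall among called genes with a mean log2 CPM of at least 2, -8.01 ± 0.28 (adjusted p = 2.07e-15). CASP5 had no count in myb36-2 NB and was at least 19.8-fold lower within run 1 (floor of 3 counts over the group), and AT1G71740, with 1 count there, was lower within run 1 by a ratio of 253 (interval 45 to 10000).

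Of the 21 tested members of the Casparian strip list, 13 fell and none rose under NB, or 14 and 1 adjusted over the list alone. Among the 13 were CASP1, CASP2, CASP5, PER64, SGN1, UCC1, DIR9, DIR16, DIR18, PER9 and PER72. The receptor gene GSO1 and the peptide genes CIF1 and CIF2, which act in the signalling that seals the strip, were not called, with log2 fold changes of -0.19 ± 0.16, -0.02 ± 0.25 and 0.04 ± 0.11. The list median was -2.92, also with genes at their bound, and -3.12 within run 1 (adjusted p = 6.8e-120, and adjusted p = 8.24e-07 with an estimated correlation). The suberin regulator gene MYB92 fell by 1.15 ± 0.18, and it was the only called member among 22 of the suberin list (adjusted p = 0.07 for the list). Other falls were in SKOR, a channel that loads potassium into the xylem (-2.37 ± 0.43, adjusted p = 0.00468), and in the laccase gene LAC3 (-1.14 ± 0.20, adjusted p = 0.00379).

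Among genes that rose in myb36-2 under NB, EARLI1 (AT4G12480), a proline-rich lipid transfer protein gene, changed by 4.15 ± 0.39 (adjusted p = 2.68e-07) and the laccase gene LAC12 by 2.16 ± 0.26 (adjusted p = 1.29e-05). The iron deficiency list was called higher: 3 of 25 members rose (7 adjusted over the list alone) and none fell, with a median of 0.56, or 0.41 within run 1 (adjusted p = 2.84e-10, and adjusted p = 0.0621 with an estimated correlation), and it was not called without the replicate block (0.153). Its called members were the regulator genes BHLH38 (2.35 ± 0.43, adjusted p = 0.00509) and BHLH100 (3.74 ± 0.73, 0.00835) and the nicotianamine synthase gene NAS1 (1.41 ± 0.30, 0.0168). BHLH100 was not called without myb36-2 NB S16 (0.0647) or S18 (0.098), nor NAS1 without S17 (0.0894) or S18 (0.0827), and BHLH38 was not called in run 1 fitted alone (0.0628). The sulfur deficiency list was called higher without any called member of 12 (median 0.45, adjusted p = 0.000982, and adjusted p = 0.336 with an estimated correlation). Phloem markers were called lower with 0 of 5 members called (median -0.58, adjusted p = 0.0092, and adjusted p = 0.077 with an estimated correlation; 3 fell adjusted over the list alone). Photosynthesis genes were called lower with 1 of 14 called (median -0.20, adjusted p = 0.00924, and adjusted p = 0.406 with an estimated correlation), and not without myb36-2 NB S17 (0.0845). Without the replicate block the sulfur (0.956), phloem (0.693) and photosynthesis (0.791) calls were lost, the last with its direction reversed. That fit mixes the difference between runs into this contrast, since myb36-2 NB came from run 1 alone. From run 1 to run 2 these lists moved by medians of 1.05, -0.62 and -0.51.

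In all, edgeR called 72 genes higher and 88 lower in myb36-2 under NB, 160 of 17262. The near balance did not hold in run 1 alone (63 higher and 141 lower) or with only the compared groups (34 and 90). Within run 1, which holds both groups, the shared-spread fit called 73 higher and 156 lower, 229 in all, of which 116 were among the 160, and the count without the replicate block was 73. Leaving out myb36-2 NB S16, S17 or S18 gave 91, 80 and 77 genes. Of the 23 called genes that the naming rule took, 21 had all 3 mutant libraries beyond all 3 Col-0 libraries of run 1, which their choice among called genes favours, and 11 kept their call without the replicate block. The other lists were not called under NB: hypoxia (1 of 12 rose), lignin (1 of 22 fell), and root cap and meristem each had an adjusted p of 0.07. Salicylic acid and nitrogen had 0.124, heat shock 0.158, ethylene 0.17, ground tissue 0.204, root hairs 0.271 and xylem 0.312. Phosphate, touch and zinc had 0.564, the clock and pattern immunity 0.577 (1 of 23 rose and 1 fell in the latter), and jasmonate 0.598. Glucosinolates, aquaporins and ABA had 0.692, auxin 0.778, and potassium, sodium, boron and copper transport 0.867 with SKOR its 1 called member of 9.

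**Figure D2:**
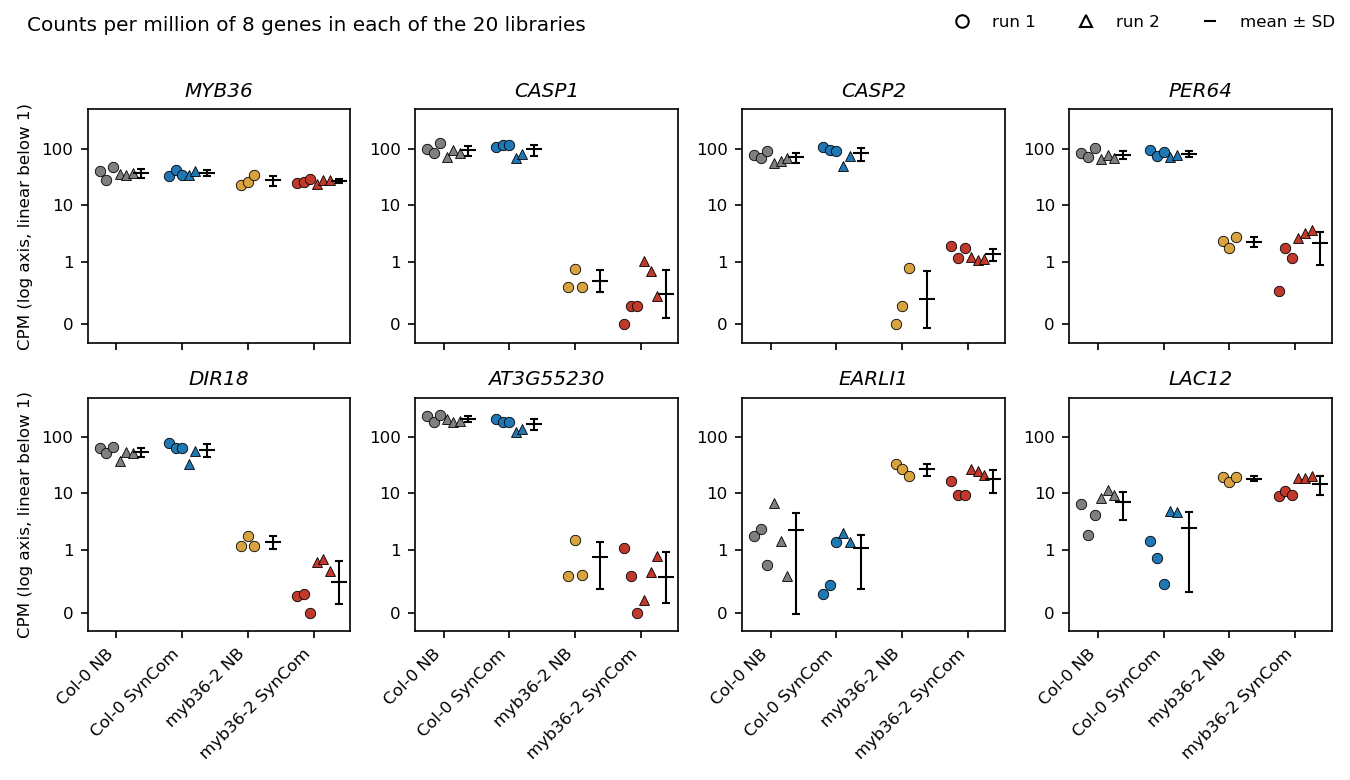
CPM of 8 genes in each of the 20 libraries by group (log axis, linear below 1), with circles for run 1, triangles for run 2 and bars for mean ± SD. MYB36 stays at 22.91 CPM or more in mutant libraries, CASP1, CASP2, PER64, DIR18 and AT3G55230 drop to a few CPM or less, and EARLI1 and LAC12 are higher in myb36-2.

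With the SynCom present, the same comparison of genotypes asks which genes differ with MYB36 on colonised plates. Casparian strip genes fell here too: 13 of 21 members fell and none rose, or 14 and 1 adjusted over the list alone. The list median was -2.30, also with genes at their bound, with -3.21 within run 1 and -1.78 within run 2 (adjusted p = 2.17e-189, and adjusted p = 1.76e-09 with an estimated correlation). CASP1 was 166-fold lower (log2 fold change -7.38 ± 0.23) and CASP2 57.3-fold (-5.84 ± 0.18), each lower in 6 of 6 mutant libraries. DIR18 changed by -6.66 ± 0.26, AT3G55230 by -8.07 ± 0.21 and MRD1 by -6.89 ± 0.25. CASP5 had no count in myb36-2 SynCom in run 1 and was at least 104-fold lower there, against a ratio of 28.5 (interval 7.26 to 246) in run 2, with 2 counts. AT1G43020, with 1 count in each run, was lower by ratios of 101 (17.8 to 4050) in run 1 and 143 (25 to 5740) in run 2. MYB92 fell by 1.05 ± 0.13 and SKOR by 1.09 ± 0.22 (adjusted p = 2.08e-05 and 0.00717).

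The largest rise in myb36-2 under SynCom, among called genes with a mean log2 CPM of at least 2, was that of the peroxidase gene PRX52 (AT5G05340), 6.42 ± 0.88 (adjusted p = 7e-05). EARLI1 rose by 3.83 ± 0.40, its neighbour and paralog AZI1 by 3.02 ± 0.48, LAC12 by 2.46 ± 0.25 and the peroxidase gene AT1G49570 by 2.06 ± 0.33, with each of the 6 mutant libraries above all Col-0 SynCom libraries of the same run. Reads shared between EARLI1 and AZI1 were not ruled out. Also higher were the ethylene synthesis gene ACS7 (1.58 ± 0.30), the phosphatase gene PAP17 (1.33 ± 0.26), the zinc transporter gene ZIP1 (0.98 ± 0.20) and the suberin gene FACT (0.57 ± 0.11). The salicylic acid genes FMO1 (1.02 ± 0.23, adjusted p = 0.0199) and ICS1 (0.72 ± 0.17, 0.022) rose. FMO1 was not called without Col-0 SynCom S36 (0.0695) or S95 (0.0644), nor ICS1 without Col-0 SynCom S36 (0.077) or myb36-2 SynCom S118 (0.0572). The cortex marker PEP fell by 0.72 ± 0.16 (adjusted p = 0.0181), a call lost without Col-0 SynCom S36 (0.077), Col-0 SynCom S94 (0.0792) or myb36-2 SynCom S48 (0.0511).

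Other lists called between genotypes under SynCom moved little, and none of these calls held with an estimated correlation. ABA response genes were higher with 0 of 22 called, 5 adjusted over the list alone (median 0.43, adjusted p = 4e-04, and adjusted p = 0.511 with an estimated correlation; medians 0.53 and 0.21 within runs 1 and 2). Touch genes were higher with 0 of 9 called (median 0.36, adjusted p = 0.00487, and adjusted p = 0.323 with an estimated correlation). Iron deficiency genes were higher with 0 of 25 called (median 0.40, adjusted p = 0.00766, and adjusted p = 0.401 with an estimated correlation; 0.10 and 0.53 within runs). Lignin genes were higher with 1 of 22 called, LAC5 (median 0.18, adjusted p = 0.0182, and adjusted p = 0.511 with an estimated correlation), and not without Col-0 SynCom S35 (0.176). LAC5 itself was not called without Col-0 SynCom S94 (0.0543). Hypoxia genes were higher with 0 of 12 called (median 0.26, adjusted p = 0.044, and adjusted p = 0.334 with an estimated correlation), and not without Col-0 SynCom S34 (0.0556) or S94 (0.0914) or myb36-2 SynCom S118 (0.0602) or S119 (0.0987). The hypoxia call was also lost without the replicate block (0.0714). Photosynthesis genes were lower with 0 of 14 called, 4 adjusted over the list alone (median -0.22, adjusted p = 0.00487, and adjusted p = 0.341 with an estimated correlation). Ground tissue markers were lower with PEP called among 4 (median -0.31, adjusted p = 0.00861, and adjusted p = 0.105 with an estimated correlation).

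Under SynCom edgeR called 141 genes higher and 146 lower in myb36-2, 287 in all. All 287 had the same sign in both runs, on which they were called together, while over all 17262 genes the log2 fold changes of the runs had a Pearson r of 0.43 and a Spearman rho of 0.19. The balance of directions differed between the runs: 64 rose and 122 fell in run 1 alone, and 216 rose and 122 fell in run 2 alone. Within run 1 the count was 233 (145 shared with the 287), within run 2 it was 227 (112 shared), and without the replicate block it was 101. It was 180 without Col-0 SynCom S36 and 185 without Col-0 SynCom S94. Of the 27 called genes named by the rule, 26 had all 6 mutant libraries beyond the Col-0 libraries of the same run, again favoured by their choice, and 17 kept their call without the replicate block. Between the NB and SynCom conditions, 61 genes fell in both and 26 rose in both, against 0.7 and 0.6 for independent calls, and 0 went opposite ways. Uncalled lists under SynCom were pattern immunity (adjusted p = 0.0622), phosphate (0.0924, 1 of 15 rose), salicylic acid (0.11, 2 of 10 rose), nitrogen (0.129), auxin (0.183), root cap and meristem (0.188) and ethylene (0.332, 1 of 9 rose). Aquaporins and heat shock had 0.37, sulfur 0.525, glucosinolates 0.532, jasmonate and zinc 0.591, and potassium, sodium, boron and copper transport 0.681. Xylem and the clock (1 of 11 rose and 2 fell) had 0.782, root hairs 0.903, suberin 0.965 (1 of 22 rose and 1 fell) and phloem 0.982.

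SynCom against NB in Col-0 asks how wild-type roots respond to the bacteria. Of the aquaporin genes, which code for water channel proteins, 13 of 19 rose and 1 fell, or 13 and 2 adjusted over the list alone, with a list call that was lost with an estimated correlation. The plasma membrane channel gene PIP2;4 rose by 1.27 ± 0.14 (1.16 in run 1 and 1.35 in run 2; adjusted p = 1.75e-06; n = 5 against 6), PIP1;1 by 0.93 ± 0.11, PIP2;2 by 0.82 ± 0.11 and the vacuolar channel gene TIP1;2 by 0.79 ± 0.10. The list median was 0.62, with 0.61 and 0.58 within runs (adjusted p = 1e-10, and adjusted p = 0.0868 with an estimated correlation). Jasmonate genes rose, 4 of 10 with none falling, among them the regulator genes MYC2 (0.73 ± 0.09) and JAZ1 (0.82 ± 0.14) and the synthesis gene AOS (0.54 ± 0.11). Their median was 0.57, with 0.56 and 0.41 within runs (adjusted p = 0.000116, and adjusted p = 0.0175 with an estimated correlation). Of the pattern immunity list 6 of 23 rose and none fell, including the peroxidase gene PER62 (1.41 ± 0.21), the transcription factor gene WRKY11 (0.60 ± 0.11) and the immune regulator gene CBP60G (0.84 ± 0.21), with a median of 0.30 (adjusted p = 0.000332, and adjusted p = 0.214 with an estimated correlation). Root hair genes had 3 of 12 rising, 5 adjusted over the list alone, with medians of 0.18 in run 1 and 0.92 in run 2 (adjusted p = 0.00404, and adjusted p = 0.33 with an estimated correlation). The root hair peroxidase gene PER73 rose by 1.15 ± 0.32 (adjusted p = 0.0189), and was not called without Col-0 NB S65 (0.0554), Col-0 NB S66 (0.053) or Col-0 SynCom S36 (0.0629).

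Outside these lists the largest rises in Col-0, among called genes with a mean log2 CPM of at least 2, were those of the cupin gene AT3G05950 (4.55 ± 0.52), the TauE-family transporter gene AT4G21250 (4.3 ± 0.53), the zinc finger gene AT3G53820 (3.85 ± 0.31) and the kinase gene CIPK13 (3.54 ± 0.29), with adjusted p values from 1.82e-08 to 5.54e-06. AT5G26320 rose by 3.42 ± 0.30 and AT2G34170 by 3.31 ± 0.26. All of these were higher in 5 of 5 SynCom libraries. In the uncalled lists, FMO1 and PBS3, genes of salicylic acid signalling, rose by 2.00 ± 0.28 and 1.51 ± 0.30, SKOR by 1.96 ± 0.24, the calmodulin-like gene CML38 by 1.91 ± 0.20 and the copper transporter gene COPT2 by 1.73 ± 0.33. The Casparian strip list was not called (adjusted p = 0.306), with 3 of 21 rising and none falling, and CASP5 changed by 1.74 ± 0.31 (2.35 in run 1 and 0.47 in run 2). Among falls were those of the acyltransferase gene PMAT1 (-2.69 ± 0.27), AT5G20790 (-2.67 ± 0.36) and the nicotianamine synthase gene NAS2 (-2.61 ± 0.44). The heat shock genes HSP23.6 (-4.95 ± 1.45, adjusted p = 0.0243) and AT1G07400 (-3.35 ± 0.91, 0.0159) fell further. HSP23.6 was not called without Col-0 NB S4 (0.172), Col-0 SynCom S34 (0.0784), S35 (0.0644) or S36 (0.094), nor AT1G07400 without Col-0 NB S4 (0.114), Col-0 SynCom S34 (0.0598) or S36 (0.0594).

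Several groups fell in Col-0 with the SynCom. Of 22 lignin genes 10 fell and none rose, 13 adjusted over the list alone, with medians of -0.51 in run 1 and -0.12 in run 2 (median -0.33, adjusted p = 1.56e-05, and adjusted p = 0.249 with an estimated correlation). Examples were the cinnamyl alcohol dehydrogenase gene CAD5 (-0.69 ± 0.12) and the laccase genes LAC5 (-0.60 ± 0.13) and LAC13 (-0.90 ± 0.20). Suberin genes had 9 of 22 falling, 10 adjusted over the list alone, and none rising (median -0.45, with -0.71 and -0.21 within runs; adjusted p = 2.59e-05, and adjusted p = 0.321 with an estimated correlation). The acyltransferase gene FACT fell by 0.58 ± 0.11, the hydroxylase gene CYP86B1 by 0.86 ± 0.19 and the transporter gene ABCG6 by 0.87 ± 0.20. In the phosphate starvation list 5 of 15 fell and 1 rose, with PAP17 at -2.04 ± 0.25 (adjusted p = 6.14e-06), PAP10 at -1.05 ± 0.21 and the phospholipase gene NPC4 at -0.95 ± 0.25. Its median was -0.42, with -0.44 and -0.48 within runs (adjusted p = 0.00141, and adjusted p = 0.0272 with an estimated correlation). Sulfur deficiency genes had 3 of 12 falling and 2 rising, and 9 falling adjusted over the list alone (median -0.60, with -0.84 and -0.13 within runs; adjusted p = 0.0106, and adjusted p = 0.348 with an estimated correlation). LSU1 fell by 2.03 ± 0.32 and the vacuolar sulfate exporter gene SULTR4;2 by 0.89 ± 0.18, while the sulfate uptake gene SULTR1;1 rose by 1.99 ± 0.39.

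Iron deficiency genes had 7 of 25 falling and 1 rising in Col-0, among them NAS2 (-3.84 in run 1 and -1.86 in run 2, lower in 5 of 5 libraries), the transporter gene OPT3 (-1.52 ± 0.35) and the regulator gene BHLH39 (-1.16 ± 0.29). The list median was -0.39 (adjusted p = 0.015, and adjusted p = 0.405 with an estimated correlation), and the call was lost without Col-0 NB S6 (0.0702). The list's response was higher in run 2 than in run 1 by a median of 0.54 (camera adjusted p = 0.0108, and 0.489 with an estimated correlation). OPT3 was called for that difference by edgeR (1.92 ± 0.52, adjusted p = 0.0497), among 2 of 25 members. ABA response genes had 3 of 22 falling and 1 rising (median -0.55, adjusted p = 0.015, and adjusted p = 0.619 with an estimated correlation). The regulator genes HB-7 and RD26 fell by 1.06 ± 0.22 and 0.61 ± 0.15, and this list was not called without Col-0 NB S4 (0.129) or Col-0 SynCom S35 (0.159). Without the replicate block the ABA list (0.0975), HB-7 (0.131) and RD26 (0.231) were not called. Hypoxia genes had 3 of 12 falling, with the fermentation gene PDC1 at -2.26 ± 0.24 (-2.03 and -2.5 within runs; median -0.79, adjusted p = 0.00164, and adjusted p = 0.0868 with an estimated correlation). Heat shock genes had 4 of 8 falling, 6 adjusted over the list alone, with medians of -3.04 in run 1 and -0.47 in run 2 (adjusted p = 0.00414, and adjusted p = 0.405 with an estimated correlation). The chaperone gene HSP90.1 fell by 2.12 ± 0.56 (adjusted p = 0.0125), and the regulator gene HSFA2 by 2.85 ± 0.69 (adjusted p = 0.00676), which was not called without Col-0 NB S4 (0.0508). Photosynthesis genes, the marker of shoot tissue, had 7 of 14 falling, 9 adjusted over the list alone (median -0.37, with -0.45 and -0.31 within runs; adjusted p = 0.00063, and adjusted p = 0.266 with an estimated correlation), with PSBO1 at -0.44 ± 0.09 and LHCB2.1 at -0.69 ± 0.16.

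In Col-0 the SynCom raised 1118 genes and lowered 1068 by edgeR, 2186 in all, of which 577 changed at least 2-fold. Of these calls, made on both runs together, 2150 had the same sign in both, while over all 17262 genes the runs had a Pearson r of 0.43 and a Spearman rho of 0.29. The count was 2870 within run 1 and 690 within run 2 (1669 and 534 of them among the 2186), and 744 without the replicate block. Of 79 called genes named by the rule, 55 had all 5 SynCom libraries beyond the NB libraries of the same run, 75 had all 5 beyond their mean, and 43 kept their call without the replicate block. The first 2 counts are favoured by the choice of these genes among called ones. Lists not called were salicylic acid (adjusted p = 0.109, 2 of 10 rose and 1 fell), touch (0.201, 3 of 9 rose and 1 fell), ethylene (0.328, 2 of 9 rose and 1 fell) and auxin (0.522, 1 of 13 rose and 1 fell). The clock had 0.795 (1 of 11 fell), ground tissue 0.837 and xylem 0.86, and zinc (1 of 7 rose and 1 fell) and glucosinolates (2 of 12 rose and 1 fell) had 0.936. The glucosinolate median was -0.61 within run 1 and 0.47 within run 2. Potassium, sodium, boron and copper transport (2 of 9 rose and 3 fell), nitrogen (3 of 12 rose and 3 fell), phloem (1 of 5 rose) and root cap and meristem had 0.967.

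**Figure D3:**
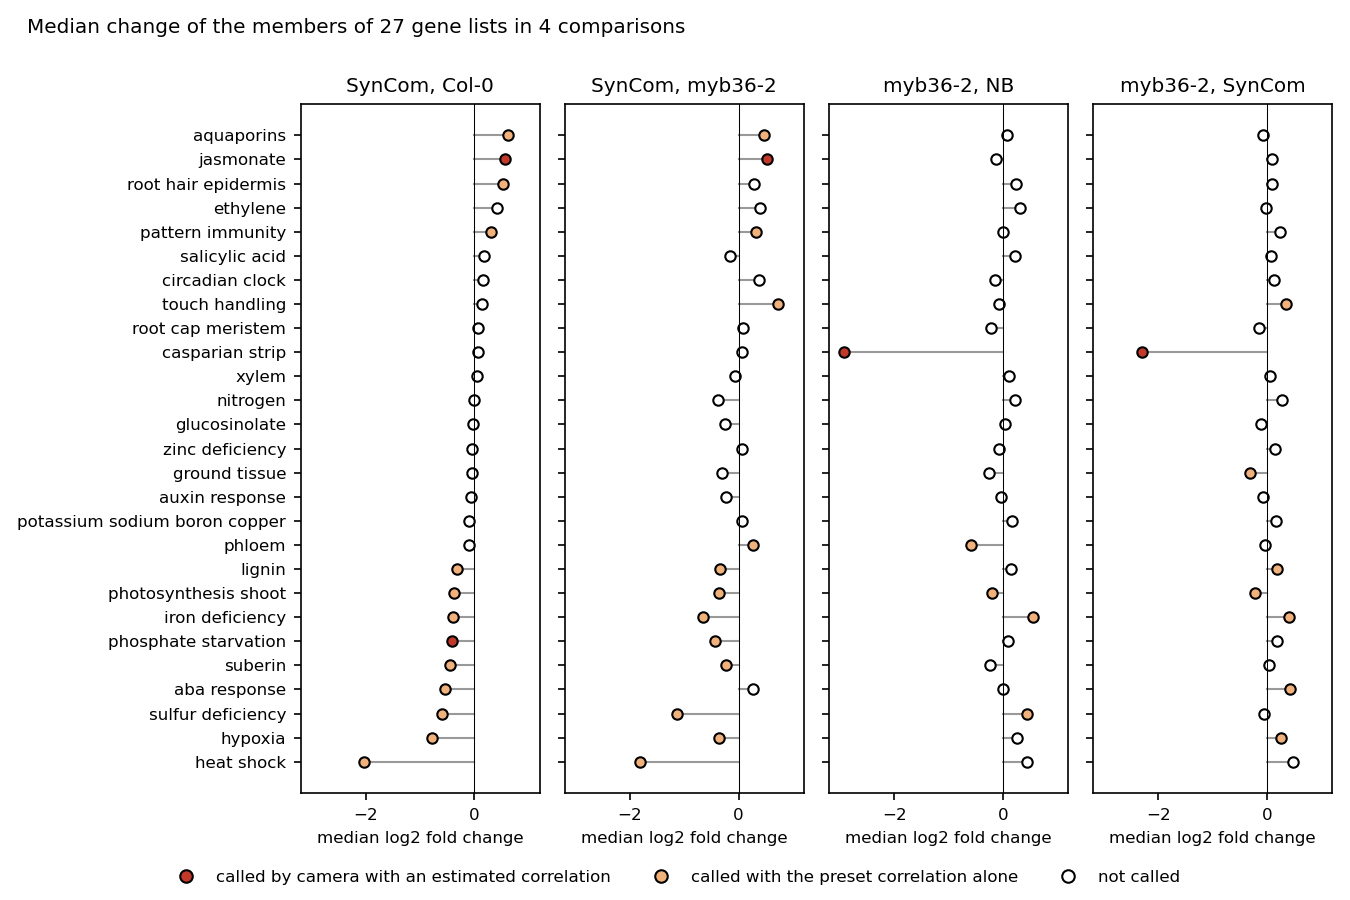
Median log2 fold change of the tested members of 27 gene lists in 4 comparisons, with fill for the camera call. The Casparian strip list has medians of -2.92 and -2.30 between genotypes and is called there with an estimated correlation too, as are jasmonate in both SynCom comparisons and phosphate starvation in Col-0.

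In myb36-2 the comparison of SynCom with NB rests on 6 and 3 libraries, the latter all from run 1. Without the replicate block, the difference between runs enters this comparison. Sulfur deficiency genes fell: 7 of 12 fell and none rose, or 9 and 1 adjusted over the list alone. LSU1 fell by 3.46 ± 0.38 (adjusted p = 2.4e-06), LSU2 by 1.43 ± 0.29, the sulfate reduction gene APR3 by 1.15 ± 0.18 and SULTR4;2 by 1.14 ± 0.21, with a list median of -1.14, or -1.15 within run 1 (adjusted p = 9.26e-08, and adjusted p = 0.0563 with an estimated correlation). Iron deficiency genes had 9 of 25 falling, 11 adjusted over the list alone, with OPT3 at -2.19 ± 0.40, BHLH39 at -1.87 ± 0.34, NAS1 at -1.71 ± 0.31 and NAS2 at -2.50 ± 0.47 (median -0.65, or -1.32 within run 1; adjusted p = 6.69e-06, and adjusted p = 0.119 with an estimated correlation). Without the replicate block that list was not called (0.079), nor were OPT3 (0.0564), BHLH39 (0.0707), NAS1 (0.876) or NAS2 (0.271). Jasmonate genes had 3 of 10 rising, 6 adjusted over the list alone, with MYC2 at 0.93 ± 0.11 and JAZ1 at 1.17 ± 0.18 (median 0.52, adjusted p = 2.67e-05, and adjusted p = 0.00905 with an estimated correlation). Aquaporins had 7 of 19 rising and 2 falling, 11 and 2 adjusted over the list alone, with PIP2;4 at 1.22 ± 0.19 and TIP1;2 at 0.78 ± 0.12 (median 0.46, adjusted p = 2.67e-05, and adjusted p = 0.2 with an estimated correlation). Pattern immunity genes had 6 of 23 rising, with the camalexin synthesis gene CYP71A13 at 3.59 ± 0.69, PER62 at 1.69 ± 0.26 and CBP60G at 1.23 ± 0.26 (median 0.33, adjusted p = 0.000189, and adjusted p = 0.133 with an estimated correlation). Touch genes had 5 of 9 rising and 1 falling, with CML38 at 2.89 ± 0.28 (adjusted p = 3.85e-07) and TCH3 at 1.35 ± 0.30 (median 0.73, adjusted p = 0.000242, and adjusted p = 0.119 with an estimated correlation).

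The largest rises in myb36-2, among called genes with a mean log2 CPM of at least 2, were those of AT4G21250, with 2 counts in NB libraries and a ratio of 62.7 within run 1 (interval 17 to 523), the RING-domain gene ARI12 with 2 counts (31.8, 8.47 to 268), AT2G41810 with 3 counts (28.2, 9.33 to 139), the oxygenase gene DIN11 (5.4 ± 0.64), the peroxidase gene AT3G03670 (5.03 ± 0.49) and AT3G60270 (4.66 ± 0.51). In the uncalled lists FMO1 rose by 2.66 ± 0.38, ICS1 by 1.23 ± 0.23, SKOR by 3.24 ± 0.40 and the nitrate uptake gene NRT3.1 by 1.31 ± 0.23, while the nitrite reductase gene NIR1 fell by 1.06 ± 0.20 and the potassium uptake gene HAK5 by 2.31 ± 0.48. Lignin genes had 5 of 22 falling, 11 adjusted over the list alone, with LAC11 at -0.69 ± 0.14 (median -0.35, adjusted p = 0.000242, and adjusted p = 0.258 with an estimated correlation). Neither the lignin list (0.182) nor LAC11 (0.0684) was called without the replicate block. Photosynthesis genes had 6 of 14 falling (median -0.36, adjusted p = 0.00321, and adjusted p = 0.258 with an estimated correlation). Hypoxia genes had 3 of 12 falling, with PDC1 at -2.35 ± 0.26 and the haemoglobin gene HB1 at -1.68 ± 0.29 (median -0.36, adjusted p = 0.00572, and adjusted p = 0.119 with an estimated correlation). Heat shock genes had 4 of 8 falling (median -1.81, adjusted p = 0.00415, and adjusted p = 0.353 with an estimated correlation). That list was not called without myb36-2 NB S16 (0.102), nor was its member HSP23.6 (-4.88 ± 1.01, adjusted p = 0.0021 with S16 and 0.1 without). The small heat shock gene AT2G29500 and the folding enzyme gene AT5G48570 fell by 3.53 ± 0.64 and 3.62 ± 0.69.

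Weaker list calls in myb36-2 were those of phloem, phosphate and suberin. None of these lists was called without the replicate block (0.931, 0.29 and 0.154). Phloem markers had 1 of 5 rising, the sucrose transporter gene SUC2 (0.85 ± 0.18; list median 0.26, adjusted p = 0.0437, and adjusted p = 0.133 with an estimated correlation). The phloem call was lost without Col-0 NB S4 (0.0571), Col-0 NB S66 (0.0529), myb36-2 NB S16 (0.0739), myb36-2 NB S17 (0.0736) or myb36-2 SynCom S118 (0.0555). Phosphate genes had 3 of 15 falling, with PHT1;4 at -1.53 ± 0.30 (median -0.43, adjusted p = 0.0437, and adjusted p = 0.133 with an estimated correlation). Their call was lost without Col-0 NB S4 (0.0571), Col-0 NB S66 (0.0535), myb36-2 NB S17 (0.0988), myb36-2 SynCom S47 (0.0607) or myb36-2 SynCom S119 (0.0582). Suberin genes had 2 of 22 falling (median -0.24, adjusted p = 0.0482, and adjusted p = 0.602 with an estimated correlation). Their call was lost without Col-0 NB S5 (0.0711), S65 (0.0675) or S66 (0.0535), Col-0 SynCom S35 (0.0664), S36 (0.053), S94 (0.0578) or S95 (0.0744), myb36-2 NB S17 (0.0988) or S18 (0.165), and myb36-2 SynCom S118 (0.0758) or S120 (0.0708).

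In myb36-2 the SynCom raised 968 genes and lowered 858 by edgeR, 1826 in all, of which 709 changed at least 2-fold. The count was 2300 within run 1 (1610 shared with the 1826) and 516 without the replicate block, and it was 1213 without myb36-2 NB S16 and 1194 without myb36-2 NB S17. Of 69 called genes named by the rule, 66 had all 3 SynCom libraries of run 1 beyond the NB libraries, which their choice among called genes favours, and 32 kept their call without the replicate block. Lists not called were root hairs (adjusted p = 0.137, 1 of 12 rose), auxin (0.161, 2 of 13 fell), the clock (0.185, 3 of 11 rose and 1 fell), ground tissue (0.307), salicylic acid (0.345, 3 of 10 rose) and glucosinolates (0.363, 1 of 12 rose). Ethylene and ABA had 0.537 (1 of 22 ABA genes fell, with a median of 0.27), root cap and meristem 0.664, potassium, sodium, boron and copper transport 0.72 (1 of 9 rose and 1 fell) and zinc 0.741 (1 of 7 rose and 1 fell). Xylem had 0.808, nitrogen 0.88 (5 of 12 rose and 4 fell) and the Casparian strip 0.983, with CASP2 called higher (1.94 ± 0.57, adjusted p = 0.0309). CASP2 was not called without myb36-2 NB S16 (0.202), myb36-2 NB S17 (0.115) or myb36-2 SynCom S46 (0.0552).

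Both genotypes responded to the SynCom with many of the same genes. Of the called genes 616 rose in both and 534 fell in both, against 62.7 and 53.1 for independent calls, and 0 went opposite ways. Across the 17262 genes, which are not independent replicates, the log2 fold changes in Col-0 and myb36-2 had a Pearson r of 0.71 and a Spearman rho of 0.57. The myb36-2 response rests on NB libraries of run 1 alone. Between runs, each with fewer libraries, the Col-0 response had a Pearson r of 0.43 and a Spearman rho of 0.29. Part of the overlap between genotypes can therefore be particular to run 1, which was not tested. Without the replicate block 150 genes rose in both and 151 fell in both, with r of 0.56 and rho of 0.31. CML38, SKOR, FMO1, MYC2, PIP2;4, NAS2, PDC1 and LSU1 were called in the same direction in both genotypes. The interaction tested whether the response itself differed between genotypes, and edgeR called 0 genes for it. Its smallest adjusted p was 0.739, 924 genes (5.4%) had an unadjusted p below 0.05, limma voom called 0 (915 unadjusted) and DESeq2 called 1 (774 unadjusted). That gene, AT2G16005, which encodes a lipid recognition domain protein and was named after its values were seen, rose from 38.3 ± 16.7 to 133 ± 19.6 CPM in Col-0 and stood at 71.7 ± 34.6 and 107 ± 41 CPM in myb36-2 NB and SynCom (SD). Its interaction was -1.75 ± 0.37 by DESeq2 (adjusted p = 0.0323) and -1.71 ± 0.36 by edgeR (adjusted p = 0.739). In simulated data the fit recovered 39.4% of 2-fold and 86.4% of 4-fold interactions.

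**Figure D4:**
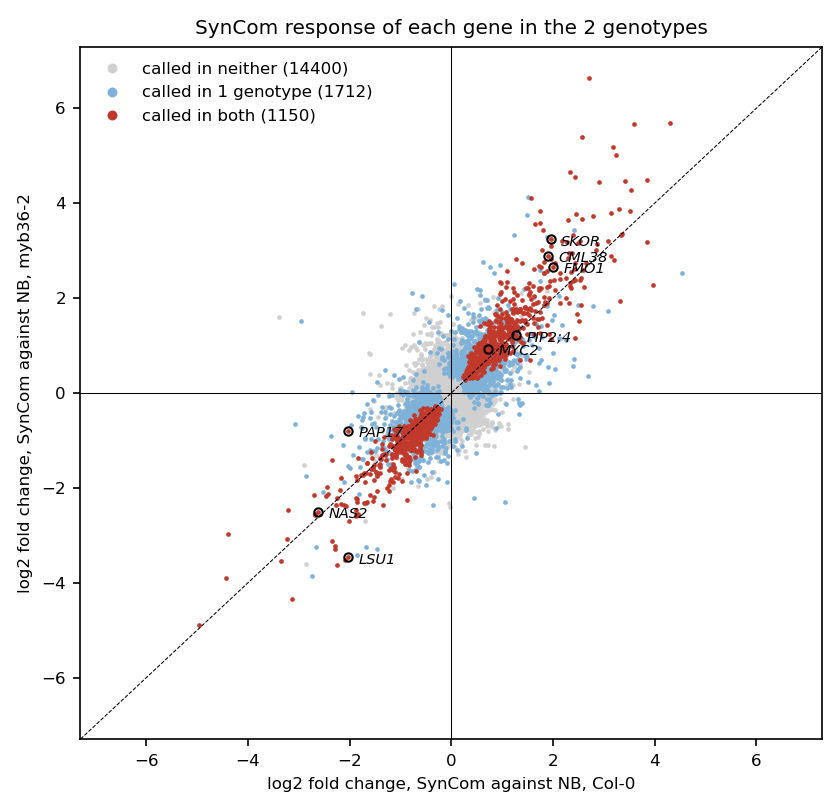
Log2 fold change of each of 17262 genes between SynCom and NB in Col-0 (horizontal axis) and in myb36-2 (vertical axis), with the dashed line marking equal values. The 1150 genes called in both genotypes all lie in the quadrants where both changes have the same sign.

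With camera, 6 lists were called for the interaction, none of them with a called member and none with an estimated correlation, and fry called 0 lists. Without the replicate block 5 of the 6 were not called (sulfur 0.903, ABA 0.994, touch 0.424, iron 0.561 and phloem 0.989), with iron and phloem in the other direction. That fit lets the difference between runs enter the interaction, since myb36-2 NB came from run 1 alone. For the same reason, the fit with the block takes the SynCom response to be alike in both runs. A difference between runs can therefore enter the interaction. In Col-0 camera called such a difference for the sulfur (median 0.9, adjusted p = 0.000107), iron (0.54, 0.0108) and suberin lists (0.42, 0.00091). None of these was called with an estimated correlation. The SynCom response in myb36-2 was below that in Col-0 for sulfur deficiency genes (median -0.54, adjusted p = 1.76e-05, and adjusted p = 0.133 with an estimated correlation) and iron deficiency genes (-0.37, adjusted p = 0.00183, and adjusted p = 0.581 with an estimated correlation). It was above that in Col-0 for ABA genes (0.41, adjusted p = 4.33e-05, and adjusted p = 0.748 with an estimated correlation), touch genes (0.40, adjusted p = 0.000358, and adjusted p = 0.133 with an estimated correlation), phloem markers (0.34, adjusted p = 0.00441, and adjusted p = 0.133 with an estimated correlation) and suberin genes (0.21, adjusted p = 0.0411, and adjusted p = 0.83 with an estimated correlation). The iron call was lost without myb36-2 NB S18 (0.0927) or myb36-2 SynCom S46 (0.0705). The suberin call was lost without Col-0 NB S4 (0.452), S6 (0.17) or S65 (0.0883), Col-0 SynCom S35 (0.268) or S36 (0.119), myb36-2 NB S16 (0.117), and myb36-2 SynCom S46 (0.0763), S47 (0.116), S48 (0.0598) or S119 (0.0702). The Casparian strip list had an adjusted p of 0.834, and the remaining 20 lists had values from 0.343 to 0.964. In run 1 fitted alone, camera called 6 lists, 5 higher and 1 lower, against 4 and 2 with all libraries. The called lists or their directions were thus not all the same.

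Over the 135 pairs of list and contrast, median or mean had another sign than the test in 19, none of them called. TMM and RLE scaling differed by at most 0.005 in the median log2 fold change of all genes. Of 208 genes that the rule names, 56 overlap another annotated gene, mostly on the opposite strand, and since the sources used here give no counting strand, their values are uncertain. Among those named above they are CASP1, CASP5, PER64, DIR9, DIR16, DIR18, MRD1, SKOR, EARLI1, MYB92, BHLH38, GSO1, PEP, MYC2, PAP10, PAP17, ZIP1, APR3, SULTR4;2, CYP71A13, TCH3, LAC11 and PER73, and CIPK13 and AT2G34170 overlap each other. MYB36 overlaps no other gene.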

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

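Tests that left out 1 run 1 NB library for the heat shock list, and the test for Col-0 material in mutant libraries, were chosen after the results were seen. Single libraries far from the rest of their group were looked for in 141 groups of values, and 9 stood apart, against 7.1 by chance, which marks about 1 in 20 groups. The myb36-2 NB libraries were not searched, since that group was too small for the rule. Both runs were pooled within a group, so the number expected by chance is only a rough guide. Of Col-0 NB libraries, S4 had 40.32 CPM of the chaperone gene HSP23.6 (others 0.61 to 12.88) and a mean log2 CPM of 4.04 for root hair genes (others 4.44 to 4.56). Col-0 NB S64 had 6.77 CPM of EARLI1 (others 0.59 to 2.36) and 12.64 CPM of PRX52 (others 0.0 to 1.19). Col-0 SynCom S94 had 0.99 CPM of HSP23.6 (others 0.0 to 0.23) and 70.17 CPM of PIP2;4 (others 90.99 to 97.49), and Col-0 SynCom S95 had 17.95 CPM of NAS2 (others 0.44 to 4.94). In myb36-2 SynCom, S46 had a mean log2 CPM of 4.38 for pattern immunity genes (others 4.79 to 4.98), and S119 had 4.6 for suberin genes (others 4.33 to 4.42).

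A response to the SynCom that differed between genotypes was called by camera for 6 lists: sulfur (adjusted p = 1.76e-05), ABA (4.33e-05), touch (0.000358), iron (0.00183), phloem (0.00441) and suberin (0.0411). None was called with an estimated correlation, of these only suberin was called without the replicate block, and edgeR called 0 single genes (924 with an unadjusted p below 0.05, 0 by limma voom and 1 by DESeq2). Since myb36-2 NB came from run 1 alone, a SynCom response that differs between runs can enter these calls. The iron call was lost without myb36-2 NB S18 (0.0927) or myb36-2 SynCom S46 (0.0705). The suberin call was lost without Col-0 NB S4 (0.452), S6 (0.17) or S65 (0.0883), Col-0 SynCom S35 (0.268) or S36 (0.119), myb36-2 NB S16 (0.117), and myb36-2 SynCom S46 (0.0763), S47 (0.116), S48 (0.0598) or S119 (0.0702). AT2G16005, chosen after its values were seen, had an adjusted p of 0.0323 by DESeq2 and 0.739 by edgeR. The difference between genotypes under SynCom differed between runs for 3 genes (1552 with an unadjusted p below 0.05), also chosen after their values were seen: OCT3, an organic cation transporter gene (2.34 ± 0.34, adjusted p = 0.00724), UCC1 (1.58 ± 0.24, 0.0118) and AGP13, an arabinogalactan protein gene (1.18 ± 0.21, 0.0491). Of 4 lists called for that difference, 0 with an estimated correlation, the Casparian strip list fell less in run 2, with UCC1 its 1 called member of 21 (median 0.65, adjusted p = 5.75e-06, and adjusted p = 0.17 with an estimated correlation).

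In Col-0 the response to the SynCom differed between runs for 441 genes (290 higher in run 2 and 151 lower) and 8 lists, 1 of them with an estimated correlation. That list, glucosinolate synthesis, had 5 of 12 genes higher and none lower, among them CYP79B3 (1.39 ± 0.23), CYP83A1 (1.33 ± 0.25) and MAM1 (1.38 ± 0.30), with a median of 0.86 (adjusted p = 7.23e-12, and adjusted p = 0.0317 with an estimated correlation). One library standing apart, Col-0 NB S5, was not the whole cause, since 436 genes were called without it, nor was depth, since 360 were called with every library thinned to the lowest total. The count was 209 without Col-0 SynCom S35, 260 without Col-0 NB S66, 176 without Col-0 SynCom S94 and 78 without Col-0 SynCom S95, where the last 2 fits keep a lone SynCom library in run 2, taken to vary like the other groups. Differences in growth, inoculation or library batch between the runs were not tested and stay open, and no biological explanation was tested.

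MYB36 stood at 58.7% to 87.9% of its Col-0 level in the 9 mutant libraries, while the 13 called Casparian strip genes had medians of at most 8.3%. These 13 were picked as called lower, and the highest of them stood at 45% to 97.3% per library. Col-0 material mixed into the mutant libraries would hold MYB36 and these genes at about the same level, and the medians of at most 8.3% argue against it. Since 0 genes annotated in TAIR10.1 overlap MYB36, reads of an annotated overlapping gene are not an explanation. Reads of unannotated transcripts were not tested. Reads shared with related MYB genes were not tested. A transcript that the myb36-2 allele still makes without a working protein may explain the pattern, as a hypothesis these counts do not settle.

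The heat shock list was lower under SynCom in run 1 (median -3.04 in Col-0 and -2.79 in myb36-2) and had a median of -0.47 in Col-0 in run 2. Median CPM of its genes in run 1 was 74.5, 16.62 and 32.38 in Col-0 NB S4, S5 and S6 and 149.5, 29.91 and 24.03 in myb36-2 NB S16, S17 and S18, against 10.49 to 18.8 in SynCom libraries. A single NB library was not the whole cause in Col-0, since the median was -2.24 without S4, -3.43 without S5 and -3.14 without S6, while in myb36-2 it was -1.58 without S16 (list call lost, 0.102), -3.07 without S17 and -3.11 without S18. Whether the response was alike in both runs stays open: the difference had an adjusted p of 0.000305 and, with an estimated correlation, 0.392, and the members HSP90.1 (2.76 ± 0.67, 0.0274) and HSP101 (2.81 ± 0.74, 0.0432) were called for it. Handling of the NB plates in run 1 could have raised these genes, and no biological explanation was tested.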

How the results depend on the processing

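The tests within run 1 or run 2 with a shared spread, and those without Col-0 NB S5 and Col-0 SynCom S35, were chosen after the data were seen. Under RLE scaling all 198 calls of named genes and all 45 list calls kept their direction and stayed past the threshold. Named genes kept their call in 194 of 198 cases with DESeq2, 160 of 197 in run 1 alone, 103 of 198 without the replicate block, and 139 of 198 whichever single library was left out. Lists did so in 31 of 45 cases in run 1 alone, 29 without the replicate block, 33 within run 1, 12 of 21 within run 2, 28 with fry, 41 without S5 and S35, 34 whichever library was left out, and 5 with an estimated correlation. Except where a reason is given, the cause was not tested.

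Without the replicate block edgeR called 744 genes for SynCom in Col-0, 516 for SynCom in myb36-2, 73 for genotype under NB and 101 for genotype under SynCom. The correlation of the SynCom responses was then 0.56, with 301 genes called in both genotypes. The block takes up the run, between which 8327 of 17262 genes differed. Without it, the run enters the contrasts with myb36-2 NB, which came from run 1 alone. Directions reversed for 2 named genes in the SynCom response of myb36-2, PAP10 (0.01, adjusted p = 0.996) and CAD4 (0.13, 0.915), and 3 among lists: photosynthesis under NB (0.791), and iron (0.561) and phloem (0.989) in the interaction.

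Run 2 alone called 924 genes for SynCom in Col-0, and within run 2 the count was 690. Run 1 alone gave 186 for genotype under SynCom with 3 lists (5 lists within run 1), but more genes than all libraries together for SynCom in Col-0 (2431) and myb36-2 (1903) and genotype under NB (204). The first technical repeat alone gave 1165 and 963 for SynCom in Col-0 and myb36-2, and 69 and 144 for genotype under NB and SynCom. Keeping only called genes with at least 2-fold change left 577, 709, 101 and 130 in that order, by construction. For genotype under SynCom, DESeq2 called 437 and the fit to only its groups 474, and DESeq2 called 1 interaction. The correlation of responses was 0.7 in run 1 alone and 0.8 with the stricter filter. Lists called with an estimated correlation numbered 2 and 1 for SynCom in Col-0 and myb36-2, 1 and 1 for genotype under NB and SynCom, and 0 for the interaction, and fry called 3 under NB and 0 for the interaction.

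Leaving out each library in turn gave 1657 to 2322 genes for SynCom in Col-0, 1194 (without myb36-2 NB S17) to 2070 for SynCom in myb36-2, 77 (without myb36-2 NB S18) to 205 for genotype under NB, 180 (without Col-0 SynCom S36) to 379 for genotype under SynCom, and 0 throughout for the interaction. Also beyond 1.5 times were 1213 for SynCom in myb36-2 without myb36-2 NB S16, 91 and 80 for genotype under NB without S16 and S17, and 185 for genotype under SynCom without Col-0 SynCom S94. Lists ranged from 12 to 14, 10 to 14, 5 to 9, 7 to 9 and 4 to 8. Fits in run 2 were not run for comparisons with myb36-2 NB, which has no library there, nor the fit to only the compared groups for the interaction, which uses all groups.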

Other observations

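Tests of other splits of the libraries were chosen after the results were seen, except those for the runs. Run 2 against run 1, which the model set aside as the replicate block, held more called genes than any contrast of the report. Among named genes, however, the largest single changes were between genotypes. Iron deficiency genes were higher in run 2, 20 of 25 with none lower (median 1.08, adjusted p = 2.08e-05, and adjusted p = 0.164 with an estimated correlation), with NAS1 at 1.93 ± 0.21 and the coumarin synthesis gene F6'H1 at 0.89 ± 0.10. All 12 glucosinolate genes were higher (median 1.08, adjusted p = 1.05e-11, and adjusted p = 0.114 with an estimated correlation), with CYP79B2 at 1.72 ± 0.10 and CYP79F2 at 2.18 ± 0.18. Sulfur deficiency genes were higher, 9 of 12 (adjusted p = 2.58e-05, and adjusted p = 0.164 with an estimated correlation), with APR1 at 1.83 ± 0.16. Root hair (8 of 12, adjusted p = 0.00412), lignin (13 of 22, 0.000415), nitrogen (7 of 12, 2 lower, 0.0224) and salicylic acid genes (7 of 10, 1 lower, 0.0418) were higher too, but not called with an estimated correlation (0.298, 0.298, 0.305 and 0.282), with COBL9 at 1.2 ± 0.12, PAL1 at 0.98 ± 0.10, the ammonium transporter gene AMT1;2 at 1.79 ± 0.18 and PBS3 at 1.85 ± 0.23.

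ABA genes were lower in run 2, 15 of 22 with none higher (median -0.86, adjusted p = 4.05e-05, and adjusted p = 0.332 with an estimated correlation), with RD29B at -3.68 ± 0.46 and RAB18 at -3.05 ± 0.45. Photosynthesis genes were lower, 10 of 14 (adjusted p = 1.88e-05, and adjusted p = 0.164 with an estimated correlation), as were all 5 phloem markers (adjusted p = 0.00107), with SUC2 at -1.52 ± 0.12, 12 of 19 aquaporins (3 higher, 0.00412), with PIP2;1 at -0.79 ± 0.07, and 6 of 9 touch genes (1 higher, 0.0198), with TCH4 at -2.11 ± 0.26. None of the last 3 lists was called with an estimated correlation (0.114, 0.332 and 0.298). The flavonoid enzyme genes FLS1 (4.83 ± 0.14), TT5 (4.23 ± 0.23) and F3H (3.68 ± 0.07) had the largest rises among the named genes. Genes named from these lists were chosen after their values were seen. The runs differed in 4168 genes higher and 4159 lower of 17262, and 12 lists were called, 0 of them with an estimated correlation. Whether growth, inoculation or sequencing differed between the runs was not tested.

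Other splits of the same libraries into groups of the same sizes were tried, with fits to only the groups of the contrast. For genes, the real split gave the most calls in 4 comparisons. SynCom in Col-0 had 1732 genes (as many in 1 of 100 splits, highest other 853). SynCom in myb36-2 had 2382 (1 of 73, highest other 1). Genotype under NB had 124 (1 of 73, highest other 38) and genotype under SynCom 474 (1 of 100, highest other 5). Since these splits also moved libraries between runs, chance is not called excluded from them. SynCom in myb36-2 and genotype under NB compare both groups in run 1 alone, with 3 libraries each. Splits within run 1 are too few there to exclude chance. The split with 853 genes set all Col-0 NB libraries but S5 together. For the runs, labels were exchanged only within a group. There 8327 genes were reached in 1 of 40 splits, with 1 the highest other, so chance is excluded for the run difference. Its 12 lists were also reached in 1 of 40, but another split gave 11, and the calls did not hold with an estimated correlation, so the lists are left open. For the interaction edgeR called 0 genes (924 with an unadjusted p below 0.05, 0 by limma voom and 1 by DESeq2), which any split reaches, so that 40 of 40 decides nothing. Another split gave 357. It set all 6 SynCom libraries of run 1 in 1 group, and so those of run 2 in the other. Its interaction therefore holds the difference in SynCom response between runs, which was called for 441 genes in Col-0. How much of the 357 this accounts for was not tested.

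With the preset correlation camera called lists in most other splits: 96 of them for SynCom in Col-0, 68 for SynCom in myb36-2, 70 and 95 for genotype under NB and SynCom, 39 for the interaction and 38 for the runs. For SynCom in Col-0 4 of 100 splits gave as many as the 13 lists, but another split gave 14, and 2 of the 13 held with an estimated correlation, so chance for the number of lists is left open there as for the runs. It is not excluded for SynCom in myb36-2 (9 lists, 12 of 73, highest other 13), genotype under NB (5, 53 of 73, 13), genotype under SynCom (10, 12 of 100, 13) or the interaction (6, 27 of 40, 10). The calls that held with an estimated correlation were the Casparian strip list between genotypes under NB (8.24e-07) and SynCom (1.76e-09), jasmonate in both SynCom comparisons (0.0175 and 0.00905) and phosphate in Col-0 (0.0272).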
